A study of Homo sapiens with 12 samples.

How the data were processed

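RNA was measured on 12 Affymetrix whole-transcript arrays, 3 for each of 4 groups: HepG2 control, HepG2 with FOXA knockdown, LS174T control and LS174T with FOXA knockdown. Per the labels' protocols, cells grew in DMEM with 10% serum, HepG2 on dishes coated with collagen. The knockdown cells were infected with lentivirus carrying short hairpin RNAs against FOXA1 and FOXA2 and went through puromycin selection for 4 days before RNA was taken. The same protocol text stands with all 12 samples. The labels describe the controls as carrying control plasmids, while the sample titles mark the controls wt and the knockdown samples sh. They do not say whether control plasmids were delivered by virus or selected. If the controls were not infected and selected, every knockdown comparison also holds the effects of infection and selection. Per the labels' protocols, total RNA was isolated with TRIZOL and an RNeasy kit, and 300 ng per sample was converted and labelled with biotin using the manufacturer's whole-transcript kits.

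The values used are the authors' deposited linear intensities, 1 per transcript cluster (called a feature here) and array, already summarised over probes. How the authors corrected background, summarised probes and normalized arrays is not given in the sources used here. The array means lay close together within a line and apart between lines, so it stays unknown whether both lines were normalized together. Levels set across the lines carry that limit. Differences between knockdown and control within a line depend on how the arrays of that line were scaled, which is unknown too. In HepG2, array medians ran from 435 to 451 in controls and from 455 to 513 in knockdown arrays. The LS174T medians overlapped, at 505 to 539 in controls and 502 to 508 in knockdown arrays. The table gave 33252 features and no detection calls, so no statement is made about whether a gene was above background. The platform annotation listed 21214 of the features, 19460 with 1 gene symbol and 1754 with several, and left 12038 unnamed here. Of the features with 1 symbol, 19429 matched a current gene identifier in the reference gene table.

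Before the data were examined, the groups, tests, alternatives, 33 gene lists and the rule for naming genes were fixed. A gene was represented by 1 feature, the one with the highest mean among those carrying only its symbol, which gave 18417 genes. For 769 genes more than 1 feature existed; features of the same gene were called in opposite directions for 16 genes in HepG2 and 10 in LS174T. Intensities were transformed as log2(value + 1), with no filter on low values and no further normalization. Changes were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes, with a mean for each group over all 12 arrays and no covariate. The tests were two-sided, Benjamini-Hochberg adjustment ran over all 18417 genes, and adjusted p below 0.05 was the threshold. The shared fit had 8 residual degrees of freedom and 4.95 prior ones. The comparisons were knockdown against control in each line, the difference of these effects between the lines, and the controls of HepG2 against those of LS174T.

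Gene lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01 between genes, with adjustment over the 32 lists that qualified. The same test with the correlation estimated for each list, and fry, were run beside it. Camera tests a list against the other genes, while fry tests it against no change, so fry answers a different question. Ranges of a list's adjusted p over the alternatives include fry. The list tests on the control comparison and 6 further lists were added after the data were seen. The names were chosen by a fixed rule: FOXA1, FOXA2 and FOXA3 always. For each knockdown, the rule took the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between groups, and the 4 largest called members of each list. For the difference between the lines it took the 6 largest each way and 2 per list, for the controls the 8 largest each way and 2 per list, and for genes changed alike in both lines the 8 largest each way by the smaller of the changes. The text leaves out some of these genes.

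The fit and the list test were tested on simulated arrays made from the real control means and residual spread of 18417 genes with normal noise, with 200 genes changed by known amounts. For the HepG2 comparison, 16% of genes changed by 0.25 on the log2 scale were recovered, 86% at 0.5, 96% at 1 and 100% at 2, with 6 false calls. For LS174T the shares were 20%, 84%, 96% and 100%, with 12 false calls, and for the difference between the lines 2%, 44%, 92% and 100%, with 2 false calls. The simulated list of 30 genes shifted by 0.3 was called in each of these comparisons, and 0 of 32 unshifted lists were. The simulated noise was independent between genes, so this does not test the list calls against correlation between genes. Only 200 single genes were changed, while 8138 and 7016 genes were called in the HepG2 and LS174T data. Benjamini-Hochberg adjustment is stricter when few genes change, so these shares do not give the recovery in the data.

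Alternatives covered quantile normalization, centring each array on its median, a filter keeping the 13131 genes at or above an intensity of 488 on at least 3 arrays, every feature instead of 1 per gene, the mean over a gene's features, a fit on only the compared groups, trended and robust moderation, array weights, the replicate number as a block, a change of at least 2-fold, log2(value + 16), and each array left out in turn. After the data were seen, 3 more were added: a test against a minimum log2 change of 0.25, leaving out small RNA genes, and leaving out LS174T control 2 and HepG2 knockdown 1 together. These arrays had the lowest array weights in their lines, 0.212 and 0.382. Python 3.11.15 with pandas 2.3.3 prepared the table, and matplotlib 3.10.9 drew the figures.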

Results

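Gene expression was measured in HepG2, a human liver cancer line that keeps many hepatocyte functions, and in LS174T, a human colon cancer line with goblet-like, mucin-producing features. In each line, 3 control samples and 3 samples carrying short hairpin RNAs against FOXA1 and FOXA2 were hybridised to 1 array each. FOXA1 and FOXA2 are forkhead transcription factors that open chromatin in endoderm-derived tissues such as liver and gut. The deposited intensities had array medians between 435 and 539 over 33252 features. Arrays of the same group correlated at r = 0.9898 to 0.9974 across genes, which are not independent replicates. The median within-group SD of a gene on the log2 scale was 0.065 in HepG2 controls, 0.092 in HepG2 knockdown, 0.107 in LS174T controls and 0.059 in LS174T knockdown arrays. With 3 arrays per group, their number limits the precision. The labels call the replicates biological without saying whether each had its own infection, so the p-values measure the spread between these arrays.

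The targeted transcripts were lower on average in the knockdown arrays of both lines, by modest amounts. FOXA1 (feature 7978706) had an intensity of 3089 ± 251 in HepG2 controls and 2612 ± 143 in HepG2 knockdown arrays (mean ± SD, n = 3 each), which is 84.5% of control. Its log2 change of -0.24 (SE 0.07) passed the test (limma adjusted p = 0.0147). In LS174T, FOXA1 went from 6145 ± 271 to 5552 ± 112, or 90.4% of control, and did not pass (log2 change -0.15, adjusted p = 0.117), although the 3 knockdown arrays lay below the 3 control arrays. FOXA2 (feature 8065344) fell in LS174T from 967 ± 101 to 707 ± 24.2, or 73.2% of control (log2 change -0.45, SE 0.08, adjusted p = 0.000669). In HepG2, FOXA2 stood at 1802 ± 131 in controls and 1622 ± 57.4 in knockdown arrays, 90.0% of control, and did not pass (log2 change -0.15, adjusted p = 0.133). The related gene FOXA3, which was not targeted, rose in HepG2 from 765 ± 55.7 to 952 ± 54.7 (log2 change 0.32, adjusted p = 0.00891), and in LS174T it had a log2 change of -0.12 (adjusted p = 0.256). The HepG2 call of FOXA1 was lost without knockdown array 1 (adjusted p = 0.0606) or control array 2 (adjusted p = 0.0678), with adjusted p between 0.00203 and 1 over all alternatives. Centring each array on its median ended the FOXA3 call (log2 change 0.19, adjusted p = 0.0987, range 0.000402 to 0.921) and brought in FOXA2 in HepG2 (log2 change -0.27, adjusted p = 0.00731, range 0.00731 to 1), which array weights also did (adjusted p = 0.0202). The upper ends for FOXA1 and FOXA3 come from the test against a minimum log2 change of 0.25, which is a different hypothesis. That test also ended the FOXA2 call in LS174T (adjusted p = 0.119).

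**Figure D1:**
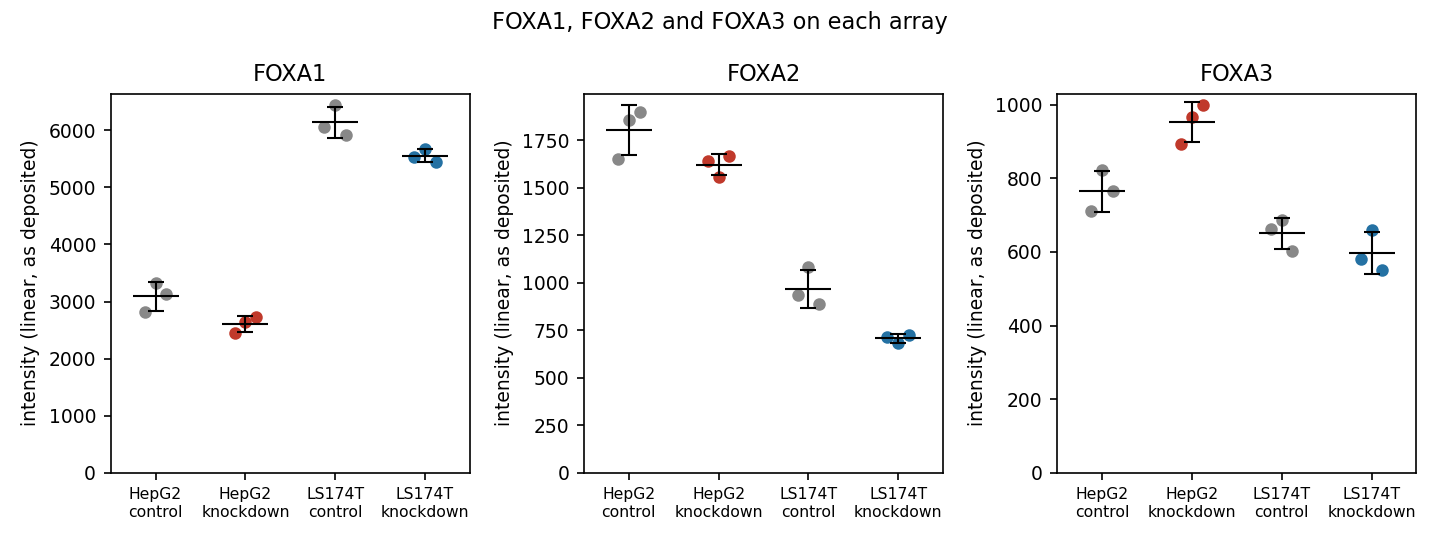
Linear intensity of FOXA1, FOXA2 and FOXA3 (vertical axes, starting at 0) on each of the 12 arrays, grouped by line and treatment; points are arrays, and the bar and whiskers are the mean and SD of 3 arrays. FOXA2 in LS174T shows the clearest fall, from 967 to 707, and FOXA1 in LS174T reaches down to only 5448.5 on the lowest knockdown array.

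In HepG2, the FOXA knockdown comparison asks which transcripts change in a liver line when FOXA1 and FOXA2 are targeted. Genes of cell division fell together: 33 of 33 measured members of the mitosis list fell (33 adjusted over the list alone), and 30 of 36 of the DNA replication list fell while 0 rose (32 and 1 adjusted over the list alone). KIF20A, a kinesin of cytokinesis, fell by 0.92 on the log2 scale (SE 0.06), CDK1, the kinase that drives entry into mitosis, by 0.89 (SE 0.09), and the spindle and chromosome regulators DLGAP5 and AURKB by 0.88 and 0.85. Among replication genes, the licensing factor CDC6 fell from an intensity of 3850 ± 324 to 1811 ± 31.2 (n = 3 each), a log2 change of -1.08. The helicase components GINS4 and MCM6 changed by -1.02 and -0.89, and the polymerase alpha subunit POLA2 by -1.01. Relative to the median of all genes, the list medians were -0.66 for mitosis and -0.73 for DNA replication (camera adjusted p = 1.09e-24 and 8.53e-23), and both passed with an estimated correlation (adjusted p = 0.0221 and 0.0261). Replication-dependent histones, made during S phase, fell in 21 of 31 genes and rose in 2 (21 and 3 adjusted over the list alone), with H2BC14 at -1.15 and H2AC14 at -1.48. Their list passed at the preset correlation (adjusted p = 4.4e-11) and had adjusted p = 0.100 with an estimated correlation.

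Lipid synthesis genes also fell in HepG2. Of 18 measured cholesterol biosynthesis genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone). The falls included the sterol reductase TM7SF2 (-0.76), mevalonate kinase MVK (-0.73), the isoprenoid isomerase IDI1 (-0.65) and the sterol transfer protein STARD4 (-0.65). Of 16 fatty acid synthesis genes, 11 fell and 0 rose (11 adjusted over the list alone), among them the lipase PNPLA3 (-0.68), the carbohydrate-responsive regulator MLXIPL (-0.67), the desaturase FADS2 (-0.52) and the acetyl-CoA synthetase ACSS2 (-0.50). Iron and haem genes fell in 11 of 22 and rose in 2 (11 and 2 adjusted over the list alone). Hepcidin, HAMP, the hormone that limits iron export, fell by 1.18 (SE 0.06) from 2814 ± 95.1 to 1237 ± 50.5. The haem pathway enzyme CPOX changed by -0.82, the ferrireductase STEAP3 by -0.54 and the iron transporter SLC11A2 by -0.53. Relative to all genes, the medians of these lists were -0.54, -0.34 and -0.26, with camera adjusted p = 3.18e-10, 6.59e-06 and 0.000239, and with an estimated correlation adjusted p = 0.0221, 0.0221 and 0.0261.

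Liver functions moved in both directions in HepG2. Of 35 measured hepatic plasma protein and apolipoprotein genes, 8 rose and 6 fell (8 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.677). The apolipoprotein APOC3 fell by 0.73 and histidine-rich glycoprotein HRG rose by 0.64. The kininogen gene KNG1 changed by -0.89 and the complement-activating protease MASP2 by -0.98, but their lists did not pass: 2 of 22 coagulation genes rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.193), and 3 of 20 complement genes rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.521). Among 29 drug-metabolising genes, 12 fell and 4 rose (12 and 4 adjusted over the list alone), with CYP3A4 at -0.96, CYP3A5 at -0.71, the oestrogen sulfotransferase SULT1E1 at -0.80 and the acetyltransferase NAT2 at -0.73. That list passed (adjusted p = 0.00266) but had adjusted p = 0.0865 with an estimated correlation. In amino acid catabolism, 13 of 27 genes fell and 6 rose (13 and 7 adjusted over the list alone), with falls of BHMT (-1.06) and AMT (-1.02) and rises of the histidine-degrading HAL (1.31) and the cystathionine lyase CTH (0.74). The list's adjusted p was 0.0211, and adjusted p = 0.170 with an estimated correlation; the low-value filter ended the call (adjusted p = 0.141, range 0.00187 to 0.17). The glucose-6-phosphate transporter SLC37A4 fell by 1.17, while the gluconeogenic PCK1 rose by 0.95 and IGFBP1, an insulin-repressed gene, by 0.80.

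Some genes of intestinal secretory cells rose in HepG2. Goblet cell and mucin genes rose in 14 of 28 and fell in 0 (14 adjusted over the list alone), with AGR2, a mucin-folding protein, from 491 ± 40.2 to 932 ± 50.7 (log2 change 0.92), AGR3 at 0.76, MUC13 at 0.60 and REG4 at 0.50. Enteroendocrine genes rose in 13 of 22 and fell in 0 (14 adjusted over the list alone), led by the transcription factor RFX6 (0.67). These lists had adjusted p = 0.00958 and 0.0211, but adjusted p = 0.438 for each with an estimated correlation, and quantile normalization ended both calls (adjusted p = 0.0552 and 0.0868, ranges 0.000418 to 0.438 and 0.00156 to 0.438). The low ends of these ranges are those of fry, which tests against no change. Rises were not particular to the goblet and enteroendocrine lists. Mesenchymal and matrix genes rose in 17 of 32 and fell in 3, though their list did not pass (camera adjusted p = 0.0619). Relative to all genes, the medians were 0.13 for goblet, 0.17 for enteroendocrine and 0.165 for mesenchymal and matrix genes. Of all 18417 genes, 5136 were called higher in HepG2. Wnt target and intestinal stem cell genes fell in 11 of 24 and rose in 2 (11 and 2 adjusted over the list alone), with the receptor ligase RNF43 at -0.80, the Wnt inhibitor NKD1 at -0.67 and ASCL2, a stem cell factor, up by 0.75. That list's adjusted p was 0.00346, and adjusted p = 0.364 with an estimated correlation.

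NF-kB genes, induced in inflammation, rose in HepG2 in 11 of 23 and fell in 1 (11 and 1 adjusted over the list alone), with RELB at 0.76, TNFAIP3 at 0.48 and IL1B at 0.46. Relative to all genes, their median was only 0.084. Fibroblast and immune cell genes stood at 0.094, and that list did not pass (camera adjusted p = 0.432). Of 25 genes of the unfolded protein response list, 8 rose and 0 fell (7 adjusted over the list alone), with PPP1R15A at 0.94, ASNS at 0.92 and ATF3 at 0.82, and the list did not pass (adjusted p = 0.0619). Interferon-response genes fell in 10 of 27 and rose in 6 (10 and 6 adjusted over the list alone), with XAF1 at -0.62 and USP18 at -0.48 against IFI27 at 0.52 and IFIT2 at 0.49. Oxidative phosphorylation genes fell in 6 of 33 and rose in 2 (4 and 2 adjusted over the list alone), with UQCRB at -0.51, NDUFA2 at -0.49 and COX7A2 at 0.37. The NF-kB, interferon and oxidative phosphorylation lists had adjusted p = 0.0455, 0.0211 and 0.0211, and adjusted p = 0.515, 0.375 and 0.798 with an estimated correlation. The NF-kB call was lost without HepG2 knockdown array 1 (adjusted p = 0.056) or 2 (0.063), HepG2 control 2 (0.0734), or LS174T control 1 (0.0531) or 2 (0.0517), the interferon call without HepG2 knockdown array 1 (0.056), and the oxidative phosphorylation call without knockdown array 3 (0.0537) or control 1 (0.101). The low-value filter ended the interferon and oxidative phosphorylation calls (0.121 and 0.141), and quantile normalization ended the latter (0.148). By fry, which tests against no change, oxidative phosphorylation did not pass (adjusted p = 0.342). Over all alternatives, the adjusted p of the NF-kB, interferon and oxidative phosphorylation lists ran from 0.00123 to 0.515, from 0.00953 to 0.375 and from 0.0075 to 0.798. The 0.00123 for NF-kB is that of fry.

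The largest single rises in HepG2 lay outside these lists. MYL3, a cardiac and slow-muscle myosin light chain, rose from 164 ± 14.2 to 2869 ± 102 (log2 change 4.13, SE 0.08). PCP2, a Purkinje cell protein, rose from 264 ± 6.0 to 4083 ± 312 (3.94, SE 0.07), and TEAD4, a DNA-binding partner of YAP, from 1458 ± 55.5 to 10705 ± 467 (2.87, SE 0.06). Probe sequences were not used here, so whether the features of MYL3, PCP2 and TEAD4 also take signal from the vector or from other transcripts is open. Both lines are labelled as infected with the same hairpin virus. MYL3 also rose in LS174T (2.83), while PCP2 and TEAD4 did not pass there. C1QL4 rose by 2.33, HPF1, a partner of PARP1 in DNA repair, by 2.03, the costimulatory receptor TNFRSF9 by 1.99 and the phospholipid-binding ANXA1 by 1.99. The metallothionein MT1F fell by 1.73, from 8040 ± 85.6 to 2422 ± 154. Small nuclear and nucleolar RNAs with falls were RNU5D-1 (-2.15), SNORD77 (-1.98) and SNORD82 (-1.80). In all, 8138 of 18417 genes were called, 5136 higher and 3002 lower, and the groups did not overlap for 55.7% of genes. For a single gene with exchangeable arrays, chance gives 10%. Genes share arrays, and a shift of whole arrays also separates groups, so this share is a description and no test. Most changes were small: 118 called genes changed at least 2-fold, 51 higher and 67 lower. The median gene changed by 0.10, and centring each array on its median moved this to -0.03 and turned the split to 2227 higher and 4467 lower, so small changes in HepG2 have no settled direction. Of 32 lists, 14 passed, 3 higher and 11 lower, and 5 passed with an estimated correlation; the 18 others had adjusted p from 0.0619 to 0.917.

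In LS174T, where the same question is asked of a colon line, the dominant change was a rise of interferon-induced genes. Of 27 measured interferon-response genes, 24 rose and 1 fell (24 and 1 adjusted over the list alone). IFIT1, which binds foreign RNA, rose from 119 ± 15.1 to 3700 ± 170 (n = 3 each), a log2 change of 4.95 (SE 0.08) or 30.9-fold. IFIT2 rose by 4.96, IFIT3 by 4.09, OASL by 3.53, IFI27 by 3.15, the chemokine CXCL10 by 3.12, IFI6 by 2.87 and the antiviral GTPase MX2 by 2.85. The list median was 1.79 relative to all genes (camera adjusted p = 2.83e-27, and adjusted p = 0.00238 with an estimated correlation). The median intensity of the list on the log2 scale lay between 8.32 and 8.64 on control arrays and between 10.65 and 10.84 on knockdown arrays.

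Stress and sterol genes rose in LS174T too. Unfolded protein response genes rose in 17 of 25 and fell in 0 (17 adjusted over the list alone), led by the stress transcription factor DDIT3, from 613 ± 86.7 to 2858 ± 65.7 (log2 change 2.23). The glutathione-degrading CHAC1 rose by 1.18, and HERPUD1 and SEL1L, of the degradation of misfolded endoplasmic reticulum proteins, by 0.90 each. The list's adjusted p was 2.81e-08, and adjusted p = 0.0517 with an estimated correlation. Cholesterol biosynthesis genes rose in 10 of 18 and fell in 0 (10 adjusted over the list alone), with the sterol sensor INSIG1 at 0.98, FDPS at 0.78, STARD4 at 0.70 and HMGCS1 at 0.68. Fatty acid oxidation and ketogenesis genes rose in 10 of 20 and fell in 0 (10 adjusted over the list alone), with ACADVL at 0.73, BDH1 at 0.58 and ECI1 at 0.49. These lists had adjusted p = 0.000547 and 0.00324, and adjusted p = 0.187 for each with an estimated correlation. Glycolysis and hypoxia genes rose in 8 of 22 and fell in 2 (8 and 2 adjusted over the list alone), with NDRG1 at 1.73, VEGFA at 1.16, PDK1 at 0.85 and ADM at 0.66. That list's adjusted p was 0.0106, and adjusted p = 0.637 with an estimated correlation; the low-value filter ended the call (adjusted p = 0.0619, range 1.74e-05 to 0.637).

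Matrix, clotting and histone genes fell in LS174T. Of 32 mesenchymal and matrix genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone), with the matricellular CCN1 at -1.24, thrombospondin THBS1 at -0.90 and fibronectin FN1 at -0.69. Coagulation and fibrinolysis genes fell in 10 of 22 and rose in 1 (12 and 1 adjusted over the list alone), with tissue factor F3 from 3122 ± 98.9 to 1410 ± 30.7 (log2 change -1.15). F9 and FGG changed by -0.61 and -0.47. In controls, 19 of the 22 genes were lower in LS174T than in HepG2 and 3 higher (median log2 difference 2.86), so many of these falls may rest on low signals. The low-value filter does not test this, as HepG2 arrays can keep such genes. Replication-dependent histones fell in 11 of 31 and rose in 0 (11 adjusted over the list alone), with H2AC8 at -0.78 and H2AC4 at -0.74. The 3 lists had adjusted p = 0.00996, 0.0142 and 0.00518, and adjusted p = 0.637 for each with an estimated correlation, and quantile normalization ended the coagulation call (adjusted p = 0.0786, range 0.00111 to 0.637). Ribosomal protein genes rose in 8 of 34 and fell in 0 (5 adjusted over the list alone), with RPL13 at 0.44 and RPL3 at 0.35, and oxidative phosphorylation genes rose in 13 of 33 and fell in 4 (13 and 4 adjusted over the list alone), with COX5B at 0.64 and SDHA at 0.56. Their adjusted p of 0.0142 each became adjusted p = 0.719 and 0.882 with an estimated correlation. Both calls were lost without LS174T control array 2 (adjusted p = 0.107 and 0.221) and with the low-value filter (0.0979 each), with ranges of 0.00587 to 0.719 and 0.00342 to 0.882. By fry, which tests against no change, oxidative phosphorylation did not pass (adjusted p = 0.0955).

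Cell type genes of the gut moved both ways in LS174T. Goblet cell and mucin genes rose in 3 of 28 and fell in 7 (3 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.851). The secreted lectin REG4 rose from 205 ± 4.9 to 1229 ± 109 (log2 change 2.57) and MUC13 by 0.79, while AGR3 fell by 0.97 and the goblet granule lectin ZG16 by 0.95. Of 28 enterocyte and colonocyte genes, 8 rose and 5 fell (8 and 7 adjusted over the list alone; adjusted p = 0.835), with CEACAM5 at 1.49 and the peptidase DPP4 at 1.21 against MS4A12 at -0.81 and carbonic anhydrase CA2 at -0.79. The chloride channel CFTR rose by 1.93, the desmosomal cadherin DSC2 by 1.44, the epithelial transcription factor ELF3 by 1.25, the Wnt-associated receptor TNFRSF19 by 1.11 and CD44 by 0.86, and the tight junction protein CLDN2 fell by 1.21. Cell division lists did not pass in LS174T: 9 of 33 mitosis genes rose and 7 fell (9 and 8 adjusted over the list alone; adjusted p = 0.821), and 5 of 36 DNA replication genes rose and 8 fell (5 and 8 adjusted over the list alone; adjusted p = 0.504). The largest falls were RPS6KA6 (-2.34), the glutathione peroxidase GPX2 (-1.88), the receptor ADGRF1 (-1.84), the TEAD cofactor VGLL3 (-1.76), LRRN1 (-1.62) and the prostaglandin receptor PTGER2 (-1.56). In all, 7016 genes were called, 3332 higher and 3684 lower, and 192 changed at least 2-fold, 142 higher and 50 lower. Groups did not overlap for 50.4% of genes, with the same limit as in HepG2. Centring each array on its median turned the split to 3657 higher and 2907 lower. Of 32 lists, 10 passed, 7 higher and 3 lower, and 1 passed with an estimated correlation; the 22 others had adjusted p from 0.135 to 0.937.

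**Figure D2:**
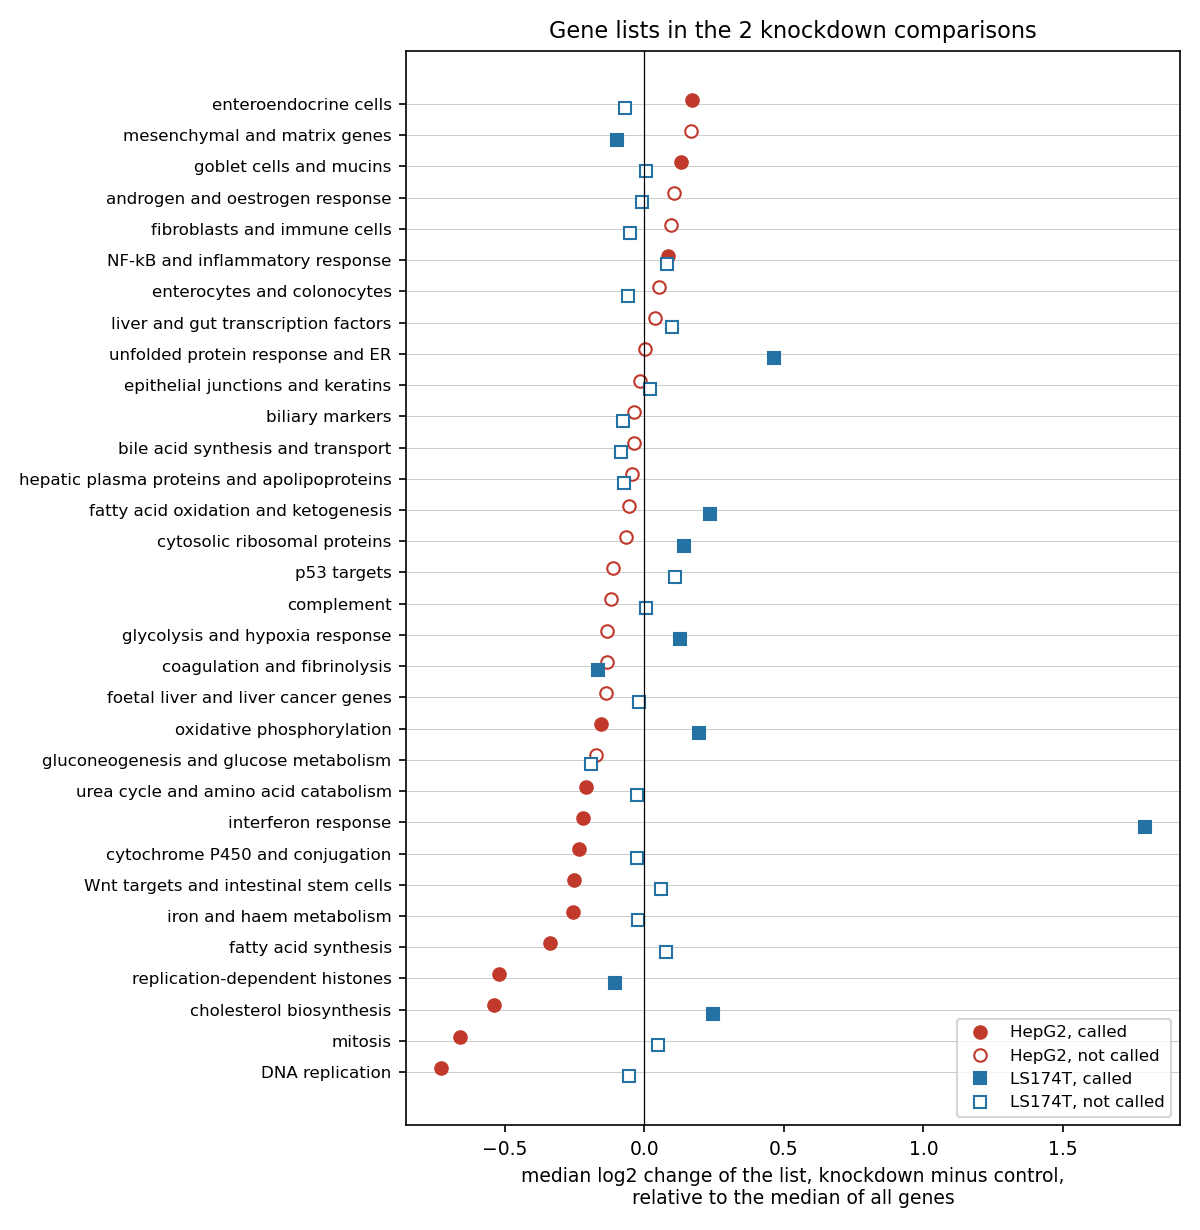
Median log2 change of each of the 32 tested gene lists (vertical axis) in HepG2 (circles) and LS174T (squares), knockdown minus control, relative to the median of all genes (horizontal axis, log2 units); filled symbols passed the camera test at the preset correlation of 0.01. The interferon list stands at 1.79 in LS174T and at -0.22 in HepG2, and mitosis at -0.66 in HepG2 and 0.05 in LS174T.

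The difference of the knockdown effect between the lines was tested directly, as HepG2 effect minus LS174T effect. Interferon genes differed most: IFIT1 by -5.10 (SE 0.12), IFIT2 by -4.46 and IFIT3 by -4.18, and 24 of 27 genes of the list were lower in this difference and 1 higher (24 and 1 adjusted over the list alone). Cholesterol biosynthesis went in opposite directions, with 16 of 18 genes lower in the difference and 1 higher (16 and 1 adjusted over the list alone). STARD4 fell by 0.65 in HepG2 and rose by 0.70 in LS174T, and FDPS fell by 0.55 and rose by 0.78. The fatty acid genes ACSS2 and SCD differed by -1.15 and -0.96. The interferon and cholesterol lists had adjusted p = 1.4e-23 and 1.52e-10, and adjusted p = 0.00399 and 0.0219 with an estimated correlation. Mitosis and DNA replication genes were lower in the difference for 29 of 33 and 26 of 36 genes and higher for 0 and 2 (30 and 27 lower, 0 and 2 higher, adjusted over the list alone). DLGAP5 differed by -1.18, NDC80 by -1.21 and GINS4 by -1.33. Their adjusted p of 5.34e-15 and 2.16e-11 became adjusted p = 0.0699 and 0.114 with an estimated correlation.

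Single genes of gut and liver function also responded differently. REG4 differed by -2.07 and rose in both lines, AGR3 by 1.74 and CA2 by 1.41, each of the latter up in HepG2 and down in LS174T. CYP3A4 differed by -1.50, with a fall of 0.96 in HepG2 and a rise of 0.54 in LS174T, and TNFRSF19 by -1.77. The BMP target ID1 differed by -2.05, the iron transporter SLC11A2 by -1.32, DDIT3 by -1.80 and CCN1 by 1.69. PCP2 (3.80), TEAD4 (2.99), WWC2-AS2 (2.43), C1QL4 (2.37) and ROCK1P1 (2.19) rose in HepG2 and did not pass in LS174T, while RPS6KA6 (2.54) fell in LS174T and did not pass in HepG2. SNORD82, SNORD77 and RNU5D-1 differed by -3.80, -3.49 and -3.41, with falls in HepG2 and rises in LS174T. FOXA1 did not differ detectably (-0.10, adjusted p = 0.429). Of 32 lists, 16 passed, 2 positive and 14 negative, and 2 passed with an estimated correlation; the 16 others had adjusted p from 0.0873 to 0.951. In all, 9373 genes differed, 5763 positive and 3610 negative, and 560 did so at least 2-fold. Centring each array on its median turned the split to 2988 positive and 5094 negative, and the median gene from 0.13 to -0.03.

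Genes changed the same way in both lines were fewer than changes in opposite directions. The numbers called higher in both and lower in both were 647 and 640, against 929 and 600 for independent lists of these sizes. Another 1117 genes were higher in HepG2 and lower in LS174T, and 863 the reverse, against 1027 and 543. Fisher's exact test over genes, which are not independent replicates, gave an odds ratio of 0.569 for higher in both (p = 3.34e-35) and 1.10 for lower in both (p = 0.0517). Among the shared rises, MYL3 changed by 4.13 in HepG2 and 2.83 in LS174T, the microRNA gene MIR21 by 1.18 and 2.26, TCP11L2 by 1.12 and 2.26, HPF1 by 2.03 and 0.85, and the proliferation-restraining factor HBP1 by 0.80 and 1.57. Shared falls included CLSPN, a replication checkpoint mediator (-0.89 and -1.08), DSCC1, a cohesion factor (-0.98 and -0.71) and the glutathione transferase GSTM4 (-0.80 and -0.85). Changes of all 18417 genes correlated at r = -0.098 (Spearman rho -0.148) across genes. At 2-fold or more in both lines, 4 genes were higher in both, MYL3, MIR21, TCP11L2 and SNORA80E, 0 were lower in both and 9 went in opposite directions, all of them small RNA genes (RNU5D-1 and 8 box C/D snoRNAs). Centring each array on its median turned the split of shared changes to 328 higher and 720 lower.

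**Figure D3:**
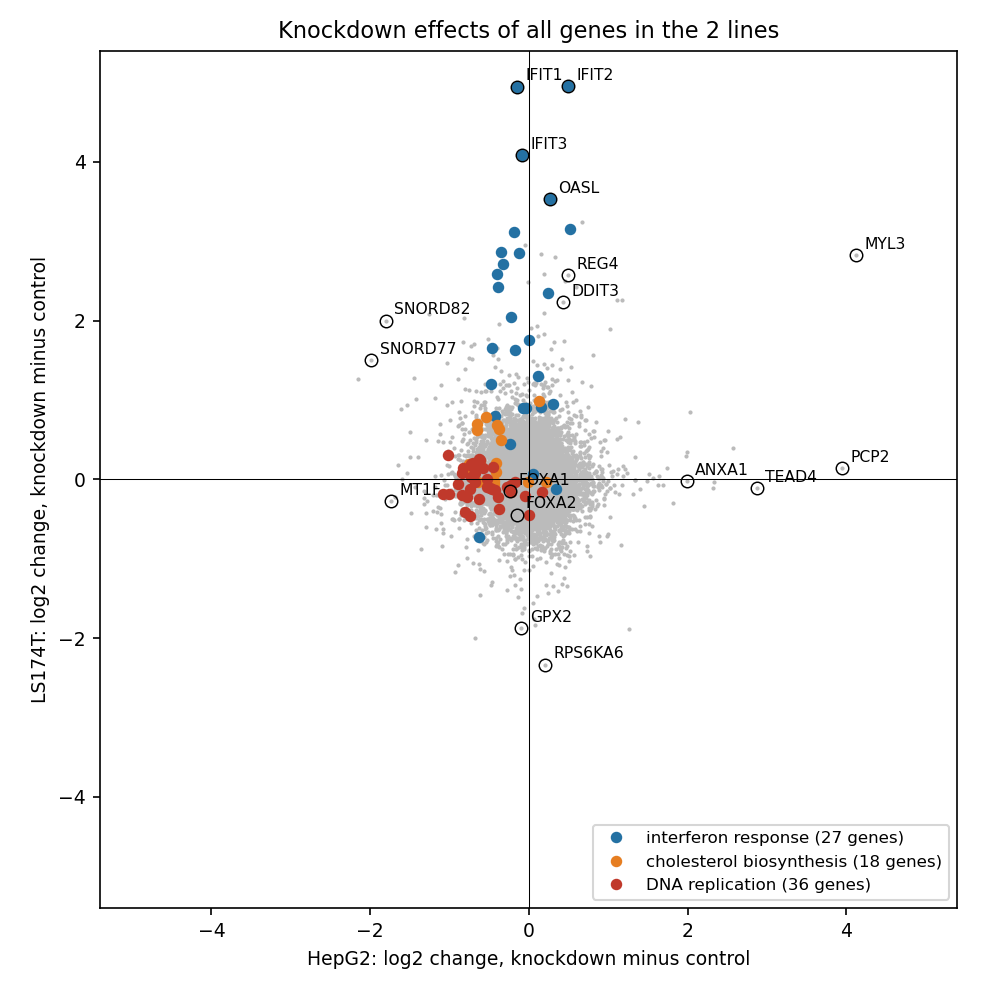
Log2 change of each of 18417 genes, knockdown minus control, in HepG2 (horizontal axis) and LS174T (vertical axis); grey dots are genes, colours mark 3 gene lists and circles mark named genes. Interferon genes spread upward along the LS174T axis, with IFIT1 at 4.95 there and -0.15 in HepG2, while MYL3 lies apart at 4.13 and 2.83.

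The controls of HepG2 and LS174T show what sets the lines apart before the knockdown, and their culture surfaces differ as well. HepG2 controls were higher for liver secretory genes: 32 of 35 hepatic plasma protein genes were higher and 1 lower (32 and 1 adjusted over the list alone). Alpha-fetoprotein AFP had an intensity of 10434 ± 307 in HepG2 and 102 ± 16.9 in LS174T (n = 3 each; log2 difference 6.68), and APOH, transferrin TF and the fibrinogen chains FGG and FGA differed by 6.06, 5.77, 5.88 and 5.47. The complement genes CFI and C3 differed by 5.24 and 5.13, and the glucuronosyltransferase UGT2B10 by 6.88. Single genes higher in LS174T controls were the intestinal transcription factor CDX2 (-4.13), the intestinal cadherin CDH17 (-4.63), CLDN7 (-4.44), TSPAN8 (-4.03), AGR2 (-3.31), ANXA1 (-5.65), OLR1 (-5.51), LDHB (-5.39) and ME1 (-5.31). Goblet cell and mucin genes were lower in HepG2 for 22 of 28 and higher for 2 (22 and 2 adjusted over the list alone). Enterocyte and colonocyte genes went the other way, with 13 of 28 higher in HepG2 and 8 lower (13 and 8 adjusted over the list alone; adjusted p = 0.0451, and adjusted p = 0.460 with an estimated correlation). FN1 and the neural cadherin CDH2 were higher in HepG2 by 4.43 and 3.72. Interferon genes were higher in HepG2 controls for 20 of 27 and lower for 6 (20 and 7 adjusted over the list alone), with IFIT2 at 3.40 and IFIT1 at 3.19, and their list had adjusted p = 0.0382 with an estimated correlation. FOXA1 was lower in HepG2 than in LS174T (log2 difference -0.99, adjusted p = 1.83e-08) and FOXA2 higher (0.90, adjusted p = 1.81e-07). The plasma protein list had adjusted p = 1.85e-21 (0.0237 with an estimated correlation), and the goblet list adjusted p = 0.00434, and adjusted p = 0.282 with an estimated correlation. In all, 14600 genes differed, 5142 higher and 9458 lower in HepG2, with no overlap for 80.1%, which is a description and no test. These levels assume that the lines were normalized alike. Centring each array on its median gave 7064 higher and 6673 lower.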

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

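The explanations in this part and the values set against them were chosen after the results were seen; quantile normalization, median centring and leaving out each array had been planned before.

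The knockdown effect differed between HepG2 and LS174T, by the test of the difference itself, for 16 gene lists. Median differences (HepG2 effect minus LS174T effect, log2) were -2.10 for interferon response, -0.84 for cholesterol biosynthesis, -0.58 for DNA replication, -0.57 for mitosis, -0.28 for fatty acid synthesis, -0.27 for iron and haem metabolism, -0.23 for fatty acid oxidation and ketogenesis and -0.21 for Wnt targets. Oxidative phosphorylation differed by a median of -0.22, the unfolded protein response by -0.20, glycolysis and hypoxia by -0.16 and replication-dependent histones by -0.13, while mesenchymal and matrix genes stood at 0.38 and enteroendocrine genes at 0.37. All these medians include the median difference of all genes, 0.13. Under median centring, the lists of the sentence before last stood, in its order, at -0.38, -0.37, -0.33, -0.29, 0.22 and 0.205. The cytochrome P450 list differed by -0.20 and cytosolic ribosomal proteins by -0.087, with adjusted p = 0.0393 and 0.0347. Only the interferon and cholesterol lists passed with an estimated correlation (adjusted p = 0.00399 and 0.0219). Quantile normalization ended the calls of enteroendocrine genes (adjusted p = 0.0741, range 0.00159 to 0.428), fatty acid oxidation (0.0698, range 0.000592 to 0.3) and ribosomal proteins (0.0741). Median centring ended those of fatty acid oxidation (0.0599) and P450 genes (0.0735). The low-value filter ended those of glycolysis (0.12, range 0.000122 to 0.428), histones (0.0956, range 0.00269 to 0.515), the unfolded protein response (0.0626, range 0.000367 to 0.272), P450 (0.211), ribosomal proteins (0.236), enteroendocrine genes (0.232) and fatty acid oxidation (0.12). By fry, which tests against no change, ribosomal proteins (adjusted p = 0.0652) and oxidative phosphorylation (0.0595) did not pass. The range for oxidative phosphorylation was 0.000283 to 0.573. The P450 call was lost without HepG2 knockdown array 1 (0.0735), HepG2 control 1 (0.0628), LS174T control 1 (0.0649) or LS174T control 3 (0.0586), with adjusted p from 0.00963 to 0.294 over the alternatives. The ribosomal call was lost without HepG2 knockdown array 3 (0.0659), HepG2 control 1 (0.0684), LS174T knockdown array 2 (0.053) or LS174T control 2 (0.0935), with a range from 0.00589 to 0.585.

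Among the 9373 genes called in that difference, the naming rule gave the 6 largest each way, beside FOXA2 and FOXA3, which were always named. The positive differences were PCP2 (3.80), TEAD4 (2.99), RPS6KA6 (2.54), WWC2-AS2 (2.43), C1QL4 (2.37), ROCK1P1 (2.19), FOXA3 (0.44) and FOXA2 (0.30). The negative ones were IFIT1 (-5.10), IFIT2 (-4.46), IFIT3 (-4.18), SNORD82 (-3.80), SNORD77 (-3.49) and RNU5D-1 (-3.41). The FOXA2 difference rests on a narrow margin (adjusted p = 0.0408, range 0.0177 to 0.681). Its call was lost without HepG2 knockdown array 1 (0.0687) or 3 (0.0862), HepG2 control 1 (0.103) or 2 (0.0506), LS174T knockdown array 1 (0.0641), 2 (0.0876) or 3 (0.0543), or LS174T control 2 (0.0769). It was also lost with the replicate number as a block (0.0725), with every feature tested (0.0624), and without LS174T control 2 and HepG2 knockdown 1 together (0.111). Median centring ended the calls of FOXA2 (0.13, adjusted p = 0.305) and FOXA3 (0.27, adjusted p = 0.0845, range 0.000556 to 0.217). The upper ends of the FOXA2 and FOXA3 ranges, 0.681 and 0.217, come from the test against a minimum log2 change of 0.25, which is a different hypothesis.

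Features with no or several gene symbols were left out of the comparisons of genes, yet 4084 of these 13792 changed in HepG2 and 3693 in LS174T when all features were tested.

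Whether chance assignment of arrays could give such counts was examined with other splits of the same arrays. For the difference between the lines, 1 of 100 drawn splits gave as many genes, the real one with 9373, and the highest other gave 3060. Splits that mix knockdown and control arrays put the knockdown change into the spread, which by itself lowers their counts. The labels do not say whether each replicate had its own infection, so the splits cannot exclude a difference between infections. For HepG2, LS174T and the controls, 10 splits of 6 arrays are too few for a share under 0.05, with real counts of 8138, 7016 and 14600 and highest others of 0, 1 and 0.

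The interferon rise in LS174T was large and had no counterpart in HepG2. It may come from a single array, but the lowest list median with 1 LS174T array left out was 1.72, against 1.75 with all arrays. Scaling between arrays was tested with quantile normalization and median centring, under which the lowest median was 1.67, so neither argues for a scaling effect. A response to the virus or to short hairpin RNA, and an effect of lower FOXA levels, cannot be told apart: the labels do not say whether the controls were infected, and the list median of -0.12 in HepG2 does not decide between them. The lines also started apart: the median log2 intensity of the list was 9.63 to 9.74 on HepG2 control arrays and 8.325 to 8.64 on LS174T ones. Whether this bears on the missing rise in HepG2 was not tested.

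Box C/D small nucleolar RNAs fell in HepG2 (median -0.55, 66 of 115 lower and 6 higher) and rose in LS174T (median 0.26, 52 higher and 11 lower), and the longer box H/ACA class moved the same ways by less (medians -0.26, 31 of 61 lower and 8 higher, and 0.18, 27 higher and 13 lower). The median gap of box C/D genes between HepG2 and LS174T went from 0.71 in the controls to -0.22 in the knockdown arrays; microRNA genes (43 of 164 higher and 11 lower in HepG2, 12 higher and 21 lower in LS174T) had medians of 0.16 and -0.09, near the medians of all genes, 0.10 and -0.04. Measured host transcripts were available for 35 of the 115 box C/D snoRNAs. These 26 hosts changed by medians of 0.069 in HepG2 and 0.042 in LS174T, with quartiles from -0.05 to 0.14 and from -0.12 to 0.13. Their 35 snoRNAs changed by -0.59 and 0.64, so host levels do not account for the changes of these 35. Box C/D snoRNAs outside this set, among them SNORD44, SNORD77, SNORD78 and SNORD79, were not covered, so hosts were not tested for the whole class. Scaling does not account for the class changes, since the LS174T median was 0.30 under median centring and 0.35 under quantile normalization. Uneven recovery of short RNA between groups may contribute or not, and cannot be told from a biological change: the Spearman correlations of length and change across 115 genes were 0.211 in HepG2 (permutation p = 0.026, adjusted 0.052 over 4 tests) and -0.295 in LS174T (p = 0.0016, adjusted 0.0064), and across 61 box H/ACA genes 0.178 (p = 0.17) and 0.012 (p = 0.93).

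FOXA1 passed in HepG2 and FOXA2 in LS174T, each with a small fall, while many genes were called; FOXA2 in HepG2 passed only under median centring and array weights. An additive background common to all features could hide a 2-fold fall only if it exceeded the values of at least 46.4% of features in the same line, which the low end of the table excludes. A shift between arrays is not enough for the counts, as 6564 genes were called in LS174T and 6694 in HepG2 after each array was centred on its median. Whether the features also take signal from other transcripts is open, since probe sequences were not used here and the lowest level left was 73.2% of control, for FOXA2 in LS174T. A knockdown that was partial when RNA was taken, effects of infection and selection, and effects of the hairpins on other targets remain untested.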

How the results depend on the processing

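No call of a gene named in the report, or of a list fixed beforehand in the knockdown comparisons and their difference, turned to the opposite direction in the alternatives run for it; list calls on the controls and of the added lists were tested only with the estimated correlation and fry beside. A minimum change of 2-fold left 118 genes in HepG2, 192 in LS174T, 560 for the difference, 3282 for the controls and 4 for the same way in both lines, by its own construction. Testing against a change of 0.25 (log2), chosen after seeing the data, gave 1198, 1658, 3060 and, for the same way in both lines, 102; many calls are thus of small changes. Every feature in place of 1 per gene gave 23540 for the controls, as more features were tested. Array weights gave 2227 genes changed the same way, and the cause was not tested. With estimated correlation, 5 lists passed in HepG2, 1 in LS174T and 2 for the difference. Camera is stricter, by its construction, where the correlation is higher. The estimates were 0.456 for oxidative phosphorylation, 0.206 for DNA replication and 0.201 for mitosis, against the preset 0.01, but 0.013 for iron and haem genes. The preset adjusted p of strongly correlated lists is thus too low if the estimates hold. With the low-value filter 9 lists passed for the difference, and the cause was not tested. Leaving out each array in turn gave 5819 to 9304 genes in HepG2, 5413 to 7483 in LS174T, 8071 to 10336 for the difference, 13961 to 14746 for the controls and 967 to 1453 the same way, with 13 to 14, 9 to 10 and 14 to 16 lists. The other alternatives moved no total by more than 1.5 times, though median centring turned the splits given in the report. Whether the replicate numbers pair the arrays is not settled, as each line has only 3 same-numbered pairs. Same-numbered arrays had correlations of deviations of -0.099, -0.182 and 0.089 in HepG2 and 0.010, 0.061 and 0.164 in LS174T. Differently numbered arrays ran from -0.215 to 0.243 in HepG2 and from -0.108 to 0.04 in LS174T. With the number as a block, 7491, 6565, 8680 and 12594 genes were called, 1155 the same way, and 14, 10 and 16 lists.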

Other observations

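The gene lists in this part were chosen after the data were seen, so their tests are no independent evidence.

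Metallothioneins, which bind zinc and copper, fell in HepG2 in 9 of 10 genes and rose in 1 (9 and 1 adjusted over the list alone; median -0.77 relative to all genes), with adjusted p = 1.22e-08 over the 6 added lists and adjusted p = 0.0567 with an estimated correlation. In LS174T, 5 of 10 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.0123, and adjusted p = 0.348 with an estimated correlation). Immediate early and AP-1 genes rose in HepG2 in 18 of 20 and fell in 0 (18 and 0 adjusted over the list alone; adjusted p = 3.62e-07, and adjusted p = 0.0567 with an estimated correlation), while in LS174T 8 rose and 8 fell (8 and 8 adjusted over the list alone). Genes of the amino acid starvation response rose in LS174T in 18 of 22 and fell in 1 (19 and 1 adjusted over the list alone), with a median of 0.65 relative to all genes (adjusted p = 2.96e-12, and adjusted p = 0.0405 with an estimated correlation), and in HepG2 in 11 of 22 with 1 fall (11 and 1 adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.445 with an estimated correlation).

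Antigen processing genes rose in LS174T in 10 of 12 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 8.13e-06, and adjusted p = 0.0405 with an estimated correlation), and in HepG2 6 of 12 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00178, and adjusted p = 0.0679 with an estimated correlation). YAP and TEAD target genes rose in HepG2 in 10 of 18 and fell in 1 (10 and 3 adjusted over the list alone; adjusted p = 0.0267, and adjusted p = 0.445 with an estimated correlation). They fell in LS174T in 10 of 18 with 0 rises (11 and 0 adjusted over the list alone; adjusted p = 4.09e-05, and adjusted p = 0.176 with an estimated correlation). The difference between the lines was higher for 11 of 18 and lower for 0 (11 and 0 adjusted over the list alone; adjusted p = 2.61e-05, and adjusted p = 0.123 with an estimated correlation). Lysosome genes did not pass in either line (adjusted p = 0.195 in HepG2 and 0.111 in LS174T), and passed for the difference between the lines (3 of 18 higher and 7 lower, 3 and 7 adjusted over the list alone; adjusted p = 0.0384, and adjusted p = 0.344 with an estimated correlation).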
